A study of Mus musculus with 2 samples.

How the data were processed

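DNase-seq maps accessible chromatin: nuclei are treated with DNase I, which cleaves open DNA more readily than packed DNA, and the cleavage ends are sequenced. Lung tissue of male mice of the hybrid strain B6CASTF1/J, aged 14 days, was assayed in 2 libraries, biological replicates 1 and 2 of 1 group. Per the labels, replicate 2 came from a pool of 3 males, while replicate 1 is labelled male with no pool named. Both carry the same donor record, so whether they share animals is not known. With 1 group there was no contrast between groups, so each comparison was made within each library and its values were set side by side.

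The authors aligned the reads to mm10, per the listings that accompany the files, and called each library on its own. The aligner, the peak caller, their versions and thresholds are not given in the sources used here. The deposited peak files hold intervals with a signal value, called the peak score below, which the authors scaled in a way the files do not state. All scores of a library were whole multiples of 1 step, 0.00707 in replicate 1 and 0.0110 in replicate 2 (tolerance 0.05 of a step). The scores were used to rank, describe or filter peaks within the list of their own library and, across libraries, only for the planned correlation over shared regions. Scores of named peaks are given for each library and not compared between libraries. Each library has a smaller and a larger peak file. The smaller was used, chosen before any test was run. Every peak of it overlapped a base at a false discovery rate of 0.001 or below, as did 98107 of the 145663 and 80467 of the 117300 peaks of the larger files. The peak files give no measured summit, so peak centres were used. The FDR files of the authors list runs of bases whose cleavage rate reached a false discovery rate of 0.05 or below. The deposited footprint files list short protected stretches, all with the constant p-value threshold 0.01 and no value of their own. No read counts are given, so the depth of each library is unknown, and no interval for read depth was computed. Binomial intervals below cover the counting of peaks or sequence matches.

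Coordinates were read with the GRCm38 sequence and the GENCODE M21 annotation, which share the coordinates of mm10. Of its genes, 32093 protein-coding and long noncoding genes gave the gene 5′ ends for peak positions and for the definition of distal peaks. Promoters, gene lists and counts per gene used the 21911 protein-coding genes among them. Each gene had the outermost 5′ end of its gene model, so that a peak at an inner transcript start did not count for its promoter. A promoter was called open when a peak lay within 1 kb of that 5′ end, and a peak near the 5′ ends of more than 1 gene counted for each. Distal peaks lay more than 1 kb from every gene 5′ end, and were counted over the gene body and 20 kb on each side. Peaks were placed, in this order, as within 1 kb of a gene 5′ end, in a coding exon, an untranslated region, a noncoding exon, an intron or between genes. Computations were made in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots with matplotlib 3.10.9.

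The 21 gene lists (325 genes, all matched by symbol), the 28 transcription factor consensus sequences, the tests and the rule for named genes were fixed before the data were examined. Peak overlap by at least 1 bp was set beside 100 random placements on the same chromosomes, and footprint overlap beside 100 random placements within peaks. The share of open promoters in each list was compared with all other protein-coding genes by Fisher's exact test, two-sided, and adjusted by the Benjamini-Hochberg method over the 21 lists in each library. The 8 lung lists together were compared with the 7 lists of other tissues in the same way. Median distal peak counts were compared with 10000 random lists of the same size matched on the decile of gene length, a two-sided permutation test with the same adjustment. Consensus sequences on both strands were counted in the 151 bp around peak centres and in windows of equal width 1000 bp away on both sides, with a two-sided exact binomial test. Footprints that held a whole consensus were compared by Fisher's exact test with windows of equal width shifted by 50 bp within the same peak. A call was an adjusted p under 0.05 in both libraries in the same direction, except for distal counts, where each library was read by itself. Genes, peaks and footprints are not independent replicates, so the p-values describe these libraries.

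Named genes were, for each list, the 3 members with a promoter peak in both libraries that ranked highest by the mean percentile of their score. To these came up to 3 members without one, in alphabetical order. For lists of other tissues 2 and 2 were taken. The 10 genes with the most shared distal peaks, the 5 highest peaks of each library and the 5 highest without a partner were also named.

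The tests were checked on simulated data. For gene lists, a run passed at an unadjusted p under 0.05 in replicate 1 alone. These rates are therefore not those of the calls, which are stricter. Random lists of 15 genes passed in 2% of 100 runs for promoters and 3% for distal peaks. Lists planted at 95% open promoters passed in 81% of runs and lists at 15% in 94%. Distal counts planted at 2 times the background passed in 43% and at 3 times in 86%. A planted consensus ratio of 2.13 was measured as 2.06, and an unplanted one of 1 as 1.16. Both used random sequence with equal base frequencies in centres and flanks. That check therefore cannot show an effect of base composition at real peak centres. Footprints shuffled within their peaks should show no preference, but 3 consensus sequences passed the test on the low side: CTCF (0.594), REST (0.192) and the NEUROD/ASCL E-box (0.176). FOXA (1.10), TEAD (1.08), AP-1 (1.01) and GATA (1.14) did not pass.

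Alternatives covered each library alone, the higher-scoring 50% of peaks, the larger peak file, other windows and flanks, all transcript 5′ ends, reciprocal overlap, random lists matched on promoter CpG content, peaks away from 5′ ends and reversed consensus sequences. No file of broad hotspots is used here, and the larger peak file took its place. Differences in peak score between the libraries by gene list were computed and left out, because the scores belong to the list of each library. Some planned items are part of the counts and are not reported here by name.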

Results

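Accessible chromatin was measured by DNase-seq in the lung of male B6CASTF1/J mice aged 14 days. The 2 libraries form 1 group: replicate 1, labelled male with no pool named, and replicate 2, from a pool of 3 males. Each library gave a list of peaks (accessible sites) and a list of footprints, short stretches within accessible DNA that were protected from cleavage. The read depth of each library is unknown, and positions are on mm10.

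Replicate 1 held 94786 accessible sites over 17.5 Mb and replicate 2 held 77403 over 14.5 Mb, a mean of 86094.5 ± 12291.6 (SD, n = 2). The strongest sites were common to both libraries: in the top decile of peak score 99.7% of replicate 1 peaks and 99.9% of replicate 2 peaks overlapped a peak of the other library. In the bottom decile the shares were 30.5% and 62.5%. Over all peaks, 73.6% of replicate 1 and 89.8% of replicate 2 had a partner, against 1.17% and 1.42% for random placements, of which none of 100 passed 1.27% and 1.51%. Across the 68824 regions with a peak in both libraries, log2 scores correlated with a Pearson coefficient of 0.940 and a Spearman coefficient of 0.926, a correlation across regions, which are not independent replicates. The larger peak files held 145663 and 117300 peaks, so the number of sites depends on the threshold of the list used.

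**Figure D1:**
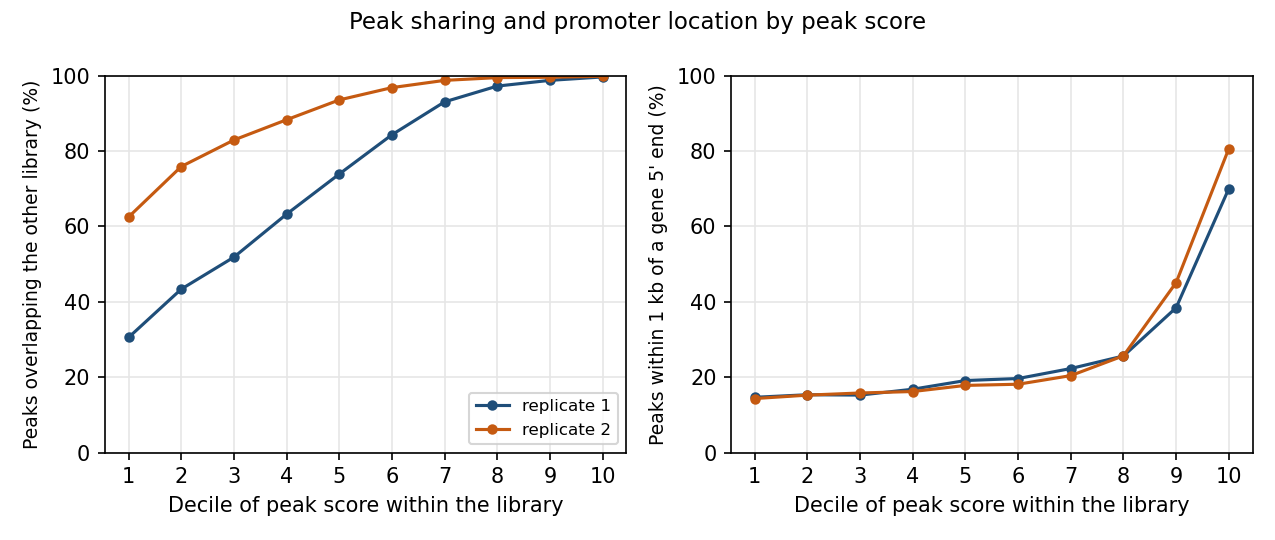
Share of peaks that overlap a peak of the other library (left, %) and share of peaks within 1 kb of a gene 5′ end (right, %), by decile of peak score within each library; each point is 1 decile of 1 library. Sharing climbs to 99.7% and 99.9% in the top decile, where 70.0% and 80.6% of peaks lie at gene 5′ ends.

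The highest peaks lay mostly at gene starts. The peak at the 5′ end of Dynlt1b (17:6430021–6430180), which encodes a light chain of the dynein motor, scored 45.0 in replicate 1 and 67.6 in replicate 2 (17:6430001–6430180). The peak near the 5′ ends of Trpm8, a cold-sensing ion channel, and Hjurp, a chaperone of centromeric histone (1:88277541–88277760), scored 44.2 and 44.8. The peak at Gm42418 (17:39846781–39846900) scored 53.3 and 42.2, and the 50 bases at its centre occurred 2 times in the assembled genome. Replicate 1 had its highest score, 57.7, between genes at X:143482981–143483120, 35540 bp from Pak3, and 50.4 in an untranslated region of Lars2, the mitochondrial leucyl-tRNA synthetase (9:123461921–123462080). Among the 5 highest of replicate 2 were also a peak at Dnpep (1:75317521–75317940), with 40.05, and a site between genes at 8:20424721–20424940, 4050 bp from Gm26804, with 36.4. No filter for regions that gather misplaced reads was applied here, so the highest scores need not all reflect accessibility.

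Sites within 1 kb of a gene 5′ end made up 25.7% of peaks in replicate 1 (exact 95% interval 25.5 to 26.0) and 26.9% in replicate 2 (26.6 to 27.3), a mean of 26.3% ± 0.859 (SD, n = 2). Random placements gave 2.58% and 2.57%, so these sites were 9.99 and 10.5 times as common as by chance. Introns held 38.4% and 37.6% of peaks, and the space between genes 29.3% in both, below the 51.5% of random placements there. Coding exons held 2.21% and 1.89% and untranslated regions 2.51% and 2.47%. Of all protein-coding genes, 61.8% had an open promoter in replicate 1 and 59.4% in replicate 2, with 12869 open in both and 8217 in neither.

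Promoters of genes known from epithelial, vessel and stromal cells of the lung were open more often than those of genes known from other tissues. The blood lists, among them the myeloid list, were in neither set, so immune cells of the lung were not covered. Of 128 lung genes, 101 were open in replicate 1 and 95 in replicate 2, and of 103 genes of liver, brain, muscle, germ line, gut, pancreas and kidney, 22 and 20 were. The difference was 57.5 and 54.8 percentage points, a mean of 56.2 ± 1.94 (SD, n = 2). Fisher's exact test gave p = 6.8e-19 in replicate 1 and p = 3.6e-17 in replicate 2. Random pairs of lists matched on promoter CpG content differed by 15.8 and 15.7 points on average, and none of 10000 differed as much (permutation p = 0.0002 in both, the smallest they can give).

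Among alveolar epithelial genes, the AT2 list (surfactant-making cells) had 12 of 15 promoters open in replicate 1 and 11 in replicate 2. Etv5, a transcription factor of AT2 cells (16:22381309–22439719), had a promoter peak at percentiles 97.1 and 99.0 of all peak scores, and Abca3, the lipid transporter of lamellar bodies (17:24351950–24410201), at 97.3 and 96.8. Muc1, a cell-surface mucin, stood at 93.8 and 89.8, while Lamp3, S100g and Slc34a2 had no peak within 1 kb of the outermost 5′ end in either library. The AT1 list (flat gas-exchange cells) had 14 and 12 of 15 open, with Vegfa, the endothelial growth factor, at percentiles 95.8 and 92.1, Rtkn2 at 93.2 and 87.5 and Hopx at 87.7 and 86.4. The Vegfa values belong to peaks that do not overlap (17:46032801–46032960 in replicate 1 and 17:46032321–46032540 in replicate 2). Cldn18, a tight junction protein, had none there and 7 and 5 distal peaks. With any annotated transcript 5′ end counted, Slc34a2 and Cldn18 had a promoter peak in at least 1 library.

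The ciliated list had 10 of 14 promoters open in both libraries, among them some of the strongest of any list: Rsph1, a radial spoke protein of cilia, at percentiles 99.8 and 98.2, Rfx2, a transcription factor of ciliogenesis, at 99.2 and 98.4, and Dnaic1, a dynein chain of the ciliary arm, at 98.0 and 98.7. Dnah5, Rsph4a and Tekt4, also parts of motile cilia, had none at the outermost 5′ end. The secretory list had 5 and 6 of 12 open, with Gsto1 at 89.4 and 85.0, Cbr2 at 55.8 and 40.7 and Aldh1a1 at 31.8 and 60.0. Bpifa1, Bpifb1 and Cldn10 had none there in either library. Regulators of lung epithelium were open in 15 and 13 of 16 cases, led by Id2 at 97.3 and 98.3, Cebpa at 97.3 and 94.6 and Klf5 at 92.2 and 93.0. Elf5 had none at its outermost 5′ end and 8 and 9 distal peaks. With any transcript 5′ end, Tekt4, Cldn10 and Elf5 had a promoter peak in at least 1 library.

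Vessel and stromal genes were open in most cases. The endothelial list had 19 of 22 promoters open in each library, with Esam, an adhesion molecule of endothelial junctions, at percentiles 90.4 and 87.6, Eng, a co-receptor for TGF-beta, at 86.1 and 88.8, and Calcrl at 85.5 and 87.6. Pecam1, the platelet and endothelial adhesion molecule, had no peak at its outermost 5′ end and 15 and 14 distal peaks, and Emcn had neither a promoter peak nor a distal peak shared by both libraries. The fibroblast and mesenchyme list had 14 of 20 open in each, led by Eln, which encodes elastin, at 94.4 and 92.2, Col1a1, a collagen chain, at 94.97 and 89.8 and Gli1, an effector of hedgehog signalling, at 89.6 and 83.1. Dcn, Fbn1 and Fgf10 had none at the outermost 5′ end, and Fbn1, which encodes fibrillin, had 13 and 11 distal peaks. The smooth muscle and pericyte list had 12 and 10 of 14 open, with Myh11 at 89.1 and 84.2, Tagln at 79.2 and 74.4 and Des at 72.7 and 70.0, and none at Higd1b. With any transcript 5′ end, Pecam1, Fbn1 and Fgf10 had a promoter peak in at least 1 library, and with a window of 2500 bp Fbn1 and Higd1b did.

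Tested list by list against all other protein-coding genes, the endothelial list was higher (86.4% in both libraries; Fisher's exact test, adjusted p = 0.026 in replicate 1 and 0.020 in replicate 2) and so was the housekeeping list (15 of 16 genes, 93.8%; adjusted p = 0.019 and 0.012). Without replicate 2, 4 lists passed: AT1 genes (exact test, adjusted p = 0.024) and epithelial regulators (0.019) did so in replicate 1 only, with 0.16 in replicate 2 for each, and the difference between the libraries was not tested. The endothelial call ended with a window of 500 or 2500 bp and with the higher-scoring 50% of peaks, while epithelial regulators were called in both libraries with 2500 bp (adjusted exact p = 0.042 and 0.021). Single lists were not tested with all transcript 5′ ends counted. Against lists matched on promoter CpG content the AT2 list (permutation, adjusted p = 0.0010 and 0.0042) and the endothelial list (0.0034 and 0.0052) were higher, and the housekeeping list was not called (0.33 and 0.23).

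Genes of blood cells were mostly without a promoter peak. The myeloid list had 5 and 2 of 17 open, with Spi1, which encodes the transcription factor PU.1, at percentiles 64.4 and 68.1 and Cd68, a macrophage protein, at 57.3 and 58.2. C1qa, C1qb and Chil3 had none. The lymphoid list had 1 and 2 of 15 open, with Cd3g, a chain of the T cell receptor complex, at 13.5 and 28.6 and none at Cd247 or, at its outermost 5′ end within 1 kb, at Cd3d, which had one with any transcript 5′ end or 2500 bp. The erythroid list had 3 of 12 open in both libraries, among them Tal1 at 67.7 and 71.8 and Epor at 66.0 and 61.3, and Alas2, Ermap and Gata1 had none. These shares were below those of other genes by Fisher's exact test, with adjusted p = 0.021 and 0.00049 for myeloid, 9.4e-05 and 0.0016 for lymphoid and 0.024 and 0.036 for erythroid genes. The erythroid call ended with a window of 500 bp (adjusted exact p = 0.061 in replicate 2) or 2500 bp (0.074 in replicate 2) and with the higher-scoring 50% of peaks (0.13 in replicate 1). None of these calls held in both libraries against lists matched on promoter CpG content, where the myeloid share lay above its matched mean in replicate 1 (29.4% against 17.6%) and below it in replicate 2 (11.8% against 15.9%).

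Genes of other tissues were also mostly closed. Hepatocyte genes had 1 of 18 promoters open in both libraries, Cyp2e1, a cytochrome of drug metabolism, at percentiles 9.11 and 6.07, and Alb and Ahsg, which encode plasma proteins, had none. Gut and pancreas genes had 1 of 15 open, Sst, which encodes somatostatin, at 12.5 and 3.91, and none at Cdx1 or Cdx2. Cardiac muscle genes had 3 of 13 open, with Tnni3 at 60.4 and 45.3 and Ryr2 at 59.1 and 39.7 and none at Actc1 or Mybpc3. Germ line genes had 2 and 3 of 14 open, with peaks at Dazl (91.6 and 90.8), an RNA-binding protein of germ cells, and Zpbp (88.6 and 88.9) and none at Ddx4 or, within 1 kb, at Acrv1, which had one within 2500 bp. Kidney tubule genes had 2 and 1 of 12 open, Cdh16 at 28.8 and 37.6 in both libraries, and none at Aqp2 or Kap.

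These 5 lists were lower than other genes in both libraries, with adjusted p by Fisher's exact test from 1.9e-05 for hepatocyte to 0.021 for cardiac muscle genes. With a window of 2500 bp the germ line share was 50% and its call ended (adjusted exact p = 0.14 and 0.80). Skeletal muscle genes (5 of 14 open in both, adjusted exact p = 0.082 and 0.15) were not called, but with 500 bp their share was 21.4% and they were called lower (0.012 and 0.028). Mylpf, a myosin light chain, stood at percentiles 94.8 and 94.0 and Ckm, a creatine kinase, at 89.1 and 81.5, while Acta1 and Myf5 had no promoter peak. For Mylpf and for Ckm the values of the libraries belong to peaks that do not overlap. Neuronal genes (8 and 6 of 17 open, adjusted exact p = 0.27 and 0.087) were not called either, with Snap25 at 85.3 and 71.8, Syn1 at 76.8 and 76.4 and none at the outermost 5′ ends of Camk2a or Dlx1, where any transcript 5′ end gave one for both and 2500 bp for Dlx1. Among housekeeping genes, Actb stood at 99.4 and 98.8, Ppia at 98.8 in both and Rpl13a at 97.1 and 99.2. Matched on promoter CpG content, hepatocyte, cardiac muscle, germ line and kidney genes were no longer called in both libraries, gut and pancreas genes still were, and neuronal genes were called lower (adjusted permutation p = 0.035 and 0.020).

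**Figure D2:**
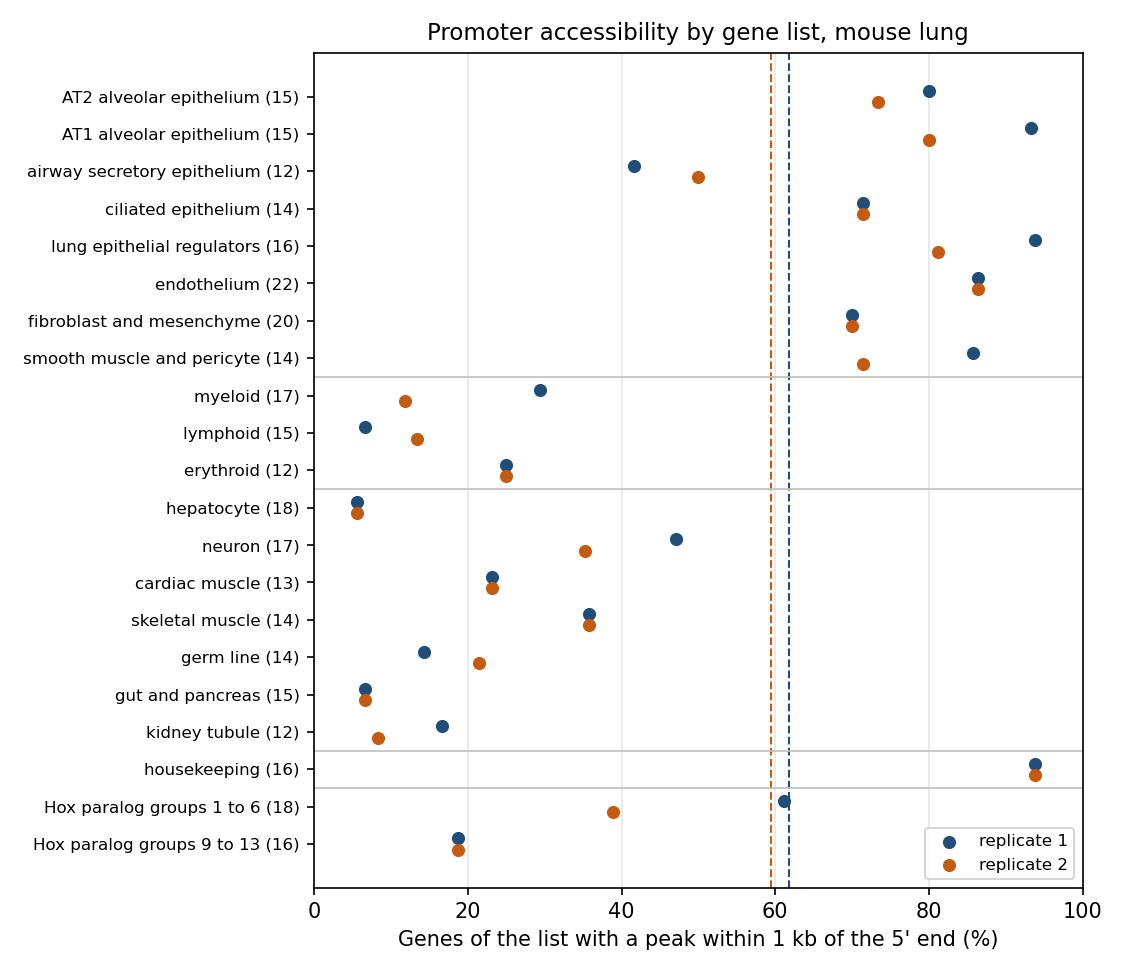
Share of promoters with a peak within 1 kb of the gene 5′ end (%), for each of the 21 gene lists with its number of genes in brackets; each point is 1 library and the dashed lines mark all protein-coding genes, 61.8% in replicate 1 and 59.4% in replicate 2. Lung lists other than airway secretory genes lie to the right of both lines, the blood and other-tissue lists lie to the left, and the housekeeping list lies at 93.8%.

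Within the Hox clusters, which encode the transcription factors of body position, genes of paralog groups 9 to 13 were mostly closed, with 3 of 16 promoters open in both libraries (lower than other genes, Fisher's exact test, adjusted p = 0.0042 and 0.0047). Hoxa10 stood at percentiles 84.6 and 68.9, Hoxc10 at 62.1 and 34.5 and Hoxc13 at 37.0 and 15.7, and Hoxa9, Hoxa11 and Hoxa13 had no promoter peak. The Hoxc13 values belong to peaks that do not overlap between the libraries. Of groups 1 to 6, 11 of 18 were open in replicate 1 and 7 in replicate 2, with Hoxa5 at 90.4 and 87.3, Hoxa4 at 91.2 and 86.4 and Hoxb5 at 85.9 and 87.3. Hoxb2, Hoxb3 and Hoxb6 had none within 1 kb of the outermost 5′ end. With any transcript 5′ end Hoxb2 and Hoxb3 had one in at least 1 library, and with 2500 bp Hoxb2 and Hoxb6 did. The difference between both sets of Hox genes passed Fisher's exact test in replicate 1 (p = 0.017) and not in replicate 2 (p = 0.27). Lists matched on promoter CpG content gave 76.2% and 73.1% for groups 1 to 6, above the 61.1% and 38.9% seen. That shortfall passed in replicate 2 only (adjusted permutation p = 0.22 and 0.0076). For groups 9 to 13 they gave 90.0% and 87.3%, and the call held (adjusted permutation p = 0.0010 and 0.0042).

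Smooth muscle and pericyte genes had a median of 6 distal peaks per gene in replicate 1 and 5.5 in replicate 2, against 2.5 and 2 in random lists of equal gene length. The permutation test passed in replicate 2 (adjusted p = 0.017) and not in replicate 1 (0.066), so that without replicate 1 the count of called lists was 1 and without replicate 2 it was 0. AT1 genes had medians of 6 and 3, epithelial regulators 5 and 1.5, endothelial genes 5 and 4 and ciliated genes 6 and 4.5, none called in either library (adjusted permutation p = 0.066 for each in replicate 1, and 0.20 or more in replicate 2). With the higher-scoring 50% of peaks endothelial and smooth muscle genes were called in both libraries (adjusted permutation p = 0.015 for each) and AT1 genes in replicate 1 (0.034). With flanks of 100 kb no list was called, and without flanks epithelial regulators and smooth muscle genes were called in replicate 1 and no list in replicate 2.

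The genes with the most distal peaks shared by both libraries mostly had long gene models. Counts cover the whole model and its flanks, so peaks of other genes inside a long model can be part of them. Gm20388 held 298 over a model of 4434.88 kb and Fgfr2, a receptor for fibroblast growth factors, 121 over 2960.9 kb, and the model of Gm20388 contains that of Gse1. Gse1 held 54, Tns1, which encodes the focal adhesion protein tensin, 48, Camta1 44, Nav2 39 and Pde4d, a phosphodiesterase of cyclic AMP, 39. Lrmda held 37 and Auts2 and Gm37240 34 each. Per 100 kb, with flanks, Tns1 had 18.9, Gse1 13.7, Fgfr2 4.03 and Pde4d 2.53.

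The consensus sequence of CTCF, the insulator protein, was 45.4 times as frequent in replicate 1 at peak centres as in the flanks (exact 95% interval 40.2 to 51.5) and 48.6 times in replicate 2 (42.4 to 56.0). REST, a repressor of neuronal genes, had ratios of 70.0 (26.7 to 260) and 38.0 (15.7 to 120) from 140 and 95 matches, and NFI 18.6 (11.1 to 33.4) and 14.0 (7.96 to 26.5). NRF1 (10.2 and 12.9), KLF/SP (10.2 and 10.5), CEBP (8.31 and 9.24), YY1 (7.60 and 6.91) and ETS (6.16 and 6.54) were also more frequent. So was RFX, a family with regulators of ciliogenesis, with 6.40 (2.24 to 22.3) and 13 (2.94 to 119). Its ratios rest on few matches, 16 at centres against 5 in flanks in replicate 1 and 13 against 2 in replicate 2.

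NKX2-1, the regulator of lung epithelium, had 1.63 in both libraries (1.46 to 1.82 and 1.45 to 1.83), FOXA 1.35 and 1.42, TEAD 1.64 and 1.66 and AP-1 1.72 in both. The ETS variant of endothelial ERG had 2.70 and 3.31 and the PU.1 sequence 2.41 and 2.77. NFY (2.36 and 2.78), the TCF21 E-box (2.88 and 3.17), the NEUROD/ASCL E-box (1.88 and 2.17) and MEF2 (1.35 in both) were also among the 20 sequences that were more frequent at centres in both libraries. CDX2, a gut factor, was less frequent (0.343 and 0.379), as was GATA (0.761 and 0.804), and SOX, RUNX, SRF, HNF1 and HNF4 were not called.

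All 27 sequences with a match were tested by exact binomial tests, adjusted together, and the POU5F1-SOX2 sequence had no match. Among the 20, the highest adjusted p was 0.00030 in replicate 1 and 0.0012 in replicate 2, both for MEF2. A consensus match is not evidence of binding, and factors of 1 family share a consensus. Among peaks more than 1 kb from gene 5′ ends the GATA call ended (mean ratio 0.919) and the mean ratios of NRF1 (4.85), ETS (2.82), YY1 (2.53), KLF/SP (6.67) and NFY (1.40) were lower but still called. Against reversed sequences ETS was at 1.33, KLF/SP at 2.48 and CEBP at 4.78, all still called, and GATA turned to 1.61. The CDX2 call ended against its reversed sequence, with 0.814 in replicate 1 (exact binomial test, adjusted p = 0.44). With 150 bp on each side CTCF was at 22.2, REST at 31.3, NFI at 9.35, CEBP at 4.54 and NRF1 at 7.23.

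**Figure D3:**
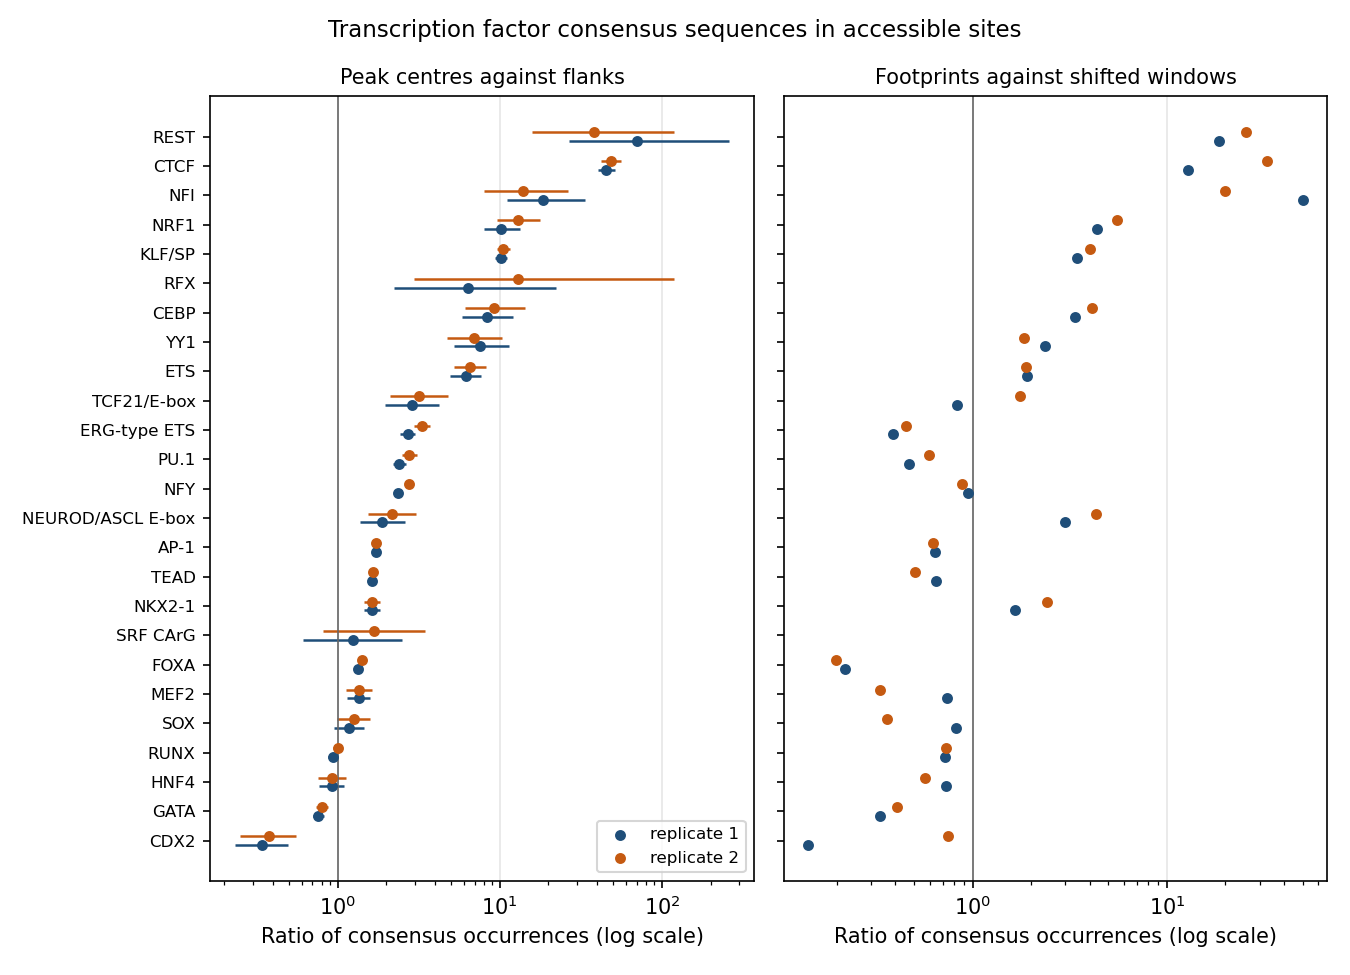
Ratio of consensus occurrences (log axes) at peak centres against flanks (left, with exact 95% intervals) and in footprints against windows shifted by 50 bp (right, without intervals), each point 1 library; not all sequences tested are drawn, and ratios of 0 or without matches in shifted windows are not drawn. CTCF, NFI and REST lie far to the right in both panels, and FOXA, TEAD, AP-1 and GATA lie below 1 in footprints.

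CTCF sequences lay wholly inside 2.40% of footprints in replicate 1 and 2.38% in replicate 2, 12.8 and 32.6 times the share in shifted windows. With positions redrawn within the same peaks its ratios were 5.05 and 6.14, and with any overlap counted 1.30 and 2.67. NFI had ratios of 50 and 20, from 100 footprints against 2 and 60 against 3, and REST 18.5 and 25.5. Redrawn positions gave 9.27 and 7.63 for NFI and 8.54 and 7.43 for REST, and any overlap 1.79 and 2.13 for NFI and 1.06 and 2.33 for REST, which was then not called in replicate 1. KLF/SP (3.44 and 4.03), NRF1 (4.37 and 5.54), CEBP (3.36 and 4.11), ETS (1.89 and 1.88), YY1 (2.37 and 1.83), NKX2-1 (1.65 and 2.40) and the NEUROD/ASCL E-box (3.00 and 4.33) were also higher, and RFX lay in 16 and 11 footprints and in no shifted window. Among those rarer in footprints were FOXA (0.220 and 0.199), GATA (0.333 and 0.410), the ERG-type ETS (0.388 and 0.455), PU.1 (0.470 and 0.597), TEAD (0.651 and 0.505), AP-1 (0.640 and 0.629) and RUNX (0.719 and 0.732).

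These calls, 11 higher and 8 lower of 28, came from 224896 and 179557 footprints by Fisher's exact test, with adjusted p under 0.05 in both libraries; the other 9 sequences were not called. With any overlap of consensus and footprint counted, the calls left were 6 higher (CTCF, NFI, CEBP, KLF/SP, NRF1 and YY1) and 1 lower (FOXA). The ratios were then 1.496 and 1.66 for KLF/SP, 1.47 and 1.73 for NRF1, 1.957 and 2.09 for CEBP, 1.47 and 1.58 for YY1, and 0.569 and 0.520 for FOXA. With positions redrawn within the same peaks calls were lost for NKX2-1 (1.25 and 1.63), YY1 (2.00 and 1.13), the NEUROD/ASCL E-box (1.06 and 2.80), PU.1 (0.556 and 0.645) and RUNX (0.629 and 0.748). PU.1 and RUNX missed the threshold in replicate 2 only (adjusted exact p = 0.061 and 0.081). Against reversed sequences 19 were higher and 0 lower: TEAD (mean ratio 5.34), AP-1 (2.55), RUNX (2.65), ERG-type ETS (2.89 and 6.00) and PU.1 (5.57 and 40, the latter from 40 matches against 1) turned and were called higher, while GATA (1.04 and 1.67) and FOXA (0.635 and 0.852) were not called in both libraries. There were 326313 footprints in replicate 1 and 252174 in replicate 2, of which 69.7% and 72.1% lay in peaks. In peaks with a partner, 63.1% and 71.2% of footprints overlapped a footprint of the other library, against 44.3% and 48.7% for random placements in those peaks.

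The X chromosome carried fewer and weaker sites than the autosomes in these male lungs. There were 13.5 peaks per Mb on X in replicate 1 and 10.7 in replicate 2, against 37.5 and 30.7 on autosomes, a ratio of 0.359 and 0.347 (mean 0.353 ± 0.00865, SD, n = 2). The median score on X was 0.636 and 0.629 of that on autosomes. Promoters were open for 44.6% and 42.6% of 948 X genes, against 63.1% and 60.7% of 20780 autosomal genes. Both libraries had 17 peaks on Y, and no test was run across the libraries.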

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

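Chosen only after the data were seen were 4 alternatives: any overlap of consensus and footprint, footprint positions redrawn within peaks, peaks up to 100 bp apart counted as shared, and random lists drawn again. No paired analysis was possible because the labels link no samples across groups. With 2 libraries, leaving 1 out places a mean at the value of the other, which says nothing about stability. Footprints carry no value of their own, so a stricter set could not be taken. Reversing the KLF/SP consensus leaves most of it intact. Read depth is unknown, so what it limits could not be computed.

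The lung against other-tissue difference stayed called under every alternative run for it. Mean peak overlap moved by less than 1 SD under every alternative, a wide margin, since the 2 shares were 73.6% and 89.8%. With reciprocal overlap they were 66.5% and 81.4%. The count of sequences higher at centres, 20, was 22 with distal peaks and 25 with reversed sequences, and 20 otherwise. Of the values that summarise a comparison, 50 stayed so and 23 moved. The 50 include single-library values of means, which count as unmoved by construction. Of single lists and sequences, 199 kept direction and call, 30 lost and 9 gained the call and 15 turned. For each that moved or turned, the cause was not tested unless it is named.

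With the higher-scoring 50% of peaks, sites numbered 43047 (by construction), the correlation of ranks was 0.892, 36.6% of peaks lay at gene 5′ ends, 1 list was higher (housekeeping), 3 passed for distal peaks and the X ratio was 0.238. The larger files held 131482 peaks. The 5′ end share was 21.3% with 500 bp, 32.6% with 2500 bp and 33.7% with all transcript 5′ ends, by the construction of these windows. Lists higher ranged from 2 to 4 over single libraries (4 without replicate 2), and 1 was left with 500 bp. Matched on promoter CpG content, 3 lists were lower instead of 9, and the myeloid share, 20.6% in the mean, lay above its expectation. Of 46 named genes without a promoter peak, 33 had none with any transcript 5′ end and 39 with 2500 bp. For distal peaks the single libraries gave 0 (without replicate 2) to 1 list, no flank gave 2 and flanks of 100 kb gave 0.

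At peak centres, distal peaks left 1 sequence lower and turned RUNX to 1.15. Reversed sequences as background left 0 lower and turned GATA (1.61), RUNX (2.38) and HNF4 (1.88). Reciprocal overlap of footprints gave 39.5%. In footprints, reversed sequences gave 19 higher and 0 lower, and turned ERG-type ETS (4.44, from 2.89 and 6.00), PU.1 (22.8, from 5.57 and 40), TEAD (5.34), AP-1 (2.55), GATA (1.35, not called), RUNX (2.65), NFY (9.48) and HNF4 (7.90, from 3.80 and 12). Any overlap with the footprint gave 6 higher and 1 lower, and turned TEAD (1.02) and RUNX (1.00). Redrawn positions gave 8 higher and 6 lower.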

Other observations

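Chosen only after the result was seen were the markers and olfactory receptors named in the next paragraph, the look at repeated sequence and neighbouring peaks, the test of the FOXA consensus alone and the use of intervals in the test of whole sequences in footprints; the bounds for X were set after the ratio over all X peaks was known.

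Some well-known lung markers lay outside the rule for named genes. Sftpc and Sftpb, which encode surfactant proteins, stood at percentiles 66.3 and 70.6 and at 71.8 and 72.5, Ager, a marker of AT1 cells, at 63.8 and 63.3, and Foxj1, the regulator of motile cilia, at 96.2 and 95.8. Kdr, a receptor for Vegfa, stood at 79.9 and 73.4. Nkx2-1 (61.9) and Acta2 (17.97) had a promoter peak in replicate 1 only, and Scgb1a1, the secretoglobin of club cells, had none and 3 distal peaks in each library. Of 1134 olfactory receptor genes, 12 had an open promoter in replicate 1 and 7 in replicate 2.

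The highest peaks without a partner lay close to a peak of the other library. In replicate 1 they were at Plag1 and Chchd7 (4:3938521–3938720), Atf3, Rbpj, Cactin and Pgrmc2, and in replicate 2 at Rab40c, Plag1 and Chchd7 (4:3938721–3938820), Pgap2 and Nup98, Ddx39b and Zswim6, all at most 80 bp from such a peak. Of all peaks without a partner, 5.16% and 8.15% lay within 100 bp of one. Of the 20 highest shared regions, 0 were more than 50% repeat sequence, against 2.16% of all shared regions. Repeats were read from the assembled genome, so sequence with copies missing from the assembly would not be seen.

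Replicate 1 had 1.22 times as many peaks as replicate 2, and greater depth is a candidate explanation, under which at least 80% of its peaks without a partner should lie over bases at an FDR of 0.05 or below in replicate 2, and under 50% if not. The share was 69.7% (exact 95% interval 69.2 to 70.3), between these bounds, and 85.4% in the other direction. If scores were scaled to the number of sequenced tags, which the files do not state, their steps of 0.00707 and 0.0110 would give replicate 1 1.56 times the tags of replicate 2. Depth cannot be told apart from other differences here, since the share lay between the bounds and no read counts are given. The number of animals, 3 pooled in replicate 2 and no pool named for replicate 1, also stays open and was not tested.

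Fewer and weaker X peaks may follow from 1 copy of X against 2 of each autosome in males. At CTCF sites with a peak in both libraries, the median score on X was 0.447 and 0.480 of that on autosomes (mean 0.463, bootstrap intervals 0.384 to 0.493 and 0.373 to 0.526), as this explanation needs. Fewer genes per Mb on X as the whole cause would leave CTCF sites away from gene 5′ ends at a ratio near 1, and their ratio was 0.473 in the mean (0.456 and 0.491), which argues against it. Peaks under the calling threshold are missing from both medians, which limits the size of the ratio. Whether reads of the hybrid genome align equally well on X and on the autosomes was not tested.

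FOXA, TEAD, AP-1 and GATA sequences were all rarer in footprints than in shifted windows, although the first 3 were more frequent at peak centres than in flanks. The requirement that the consensus lies wholly inside the footprint could account for part: with any overlap counted, 0 of the 4 reached a ratio of 1 in both libraries and 3 lay below 1 in both, which by the values alone would argue against it, but the intervals of TEAD, AP-1 and GATA included 1. For FOXA alone the ratio stayed at 0.544 in the mean (0.569 and 0.520, upper bounds 0.642 and 0.593), which argues against that requirement as its whole cause. For base composition of footprints, the reversed sequence was also rarer in footprints for each of the 4. It lay above the interval of the consensus in both libraries for 1 of the 4, FOXA (0.356 and 0.277). It lay inside the interval for GATA (0.386 and 0.250), as composition would give. For TEAD (0.472 and 0.352) and AP-1 (0.504 and 0.401) it lay below, rarer than the consensus itself, so composition could account for their low ratios. Neither bound for the 4 together was met, so composition cannot be told apart from the other causes. No biological explanation of these footprint ratios was tested.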
